A study of Gossypium hirsutum with 6 samples.

How the data were processed

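RNA was measured in roots of upland cotton (Gossypium hirsutum, an allotetraploid with an A and a D subgenome). Plants had been kept for 9 days with 0 or 300 mg/l of PS-COOH, the usual abbreviation of carboxyl-modified polystyrene. Each group holds 3 libraries, sequenced as 150-bp paired-end reads per the labels' protocols. The libraries were assigned to the control or the PS-COOH group by their titles. The labels do not say whether libraries of a group came from separate plants or cultures, so p-values measure the spread between these libraries, which may be technical.

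The authors deposited 1 table of FPKM values (fragments mapped to a gene, scaled by its transcript length and by the mapped fragments of the library), with 81166 identifiers and 6 columns, all of which were used. HISAT2 and StringTie are named in the submitters' processing notes, without versions or roles. The genome build, the annotation, the filters and the treatment of reads that match several genes are not given in the sources used here. FPKM corrects for gene length and for the total number of fragments, but it makes no further correction when a few abundant genes change between groups. Of the identifiers, 36118 carry a chromosome code of the A subgenome and 38784 one of the D subgenome, 474 carry a scaffold code and 5790 are called newGene.

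The table gives no gene names. A RefSeq table of 99454 cotton genes was searched by gene number, current and older locus tag, symbol, synonym, Ensembl identifier, and transcript and protein accession, and 0 of the identifiers matched. The 40 gene lists fixed before the data were examined (oxidative stress enzymes, cell wall, hormones, transporters, transcription factors, shoot tissue and RNA quality markers, and others) therefore could not be formed, and no gene list was tested. For the same reason no gene function, coordinate or homoeologous pair is given. Identifiers were grouped by the chromosome code they carry. Identifiers of 1 chromosome were put in number order, which is taken to follow their position.

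The files give no read counts, so absolute depth is unknown and no counting interval is given for an FPKM value. Relative depth was read from the low end of the table. Among genes under 0.1 FPKM in both of 2 libraries, the ratio of the values piles up at the ratio of what 1 fragment is worth. In bins of 0.02 on the log2 scale the peak held 37 to 47 genes, against a median of 8 per bin. By this measure the control libraries had relative depths of 1, 0.998 and 0.975, and the PS-COOH libraries 1.05, 1.10 and 1.05, all relative to control replicate 1.

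The planned test was a limma moderated test (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1), with an abundance trend in the prior variance, no covariate and Benjamini-Hochberg adjustment. It was run on the 45258 identifiers with at least 1 FPKM in at least 3 of the 6 libraries. Genes past an adjusted p of 0.05 are said to have risen or fallen, and a second count asked also for a change of at least 1 on the log2(FPKM + 1) scale, called 2-fold here. That scale understates the change of low genes. A simulation drew independent normal values with the real means and with spreads shrunk by limma's own model. Changes were placed only in genes with a mean above 2 on the log2(FPKM + 1) scale. There the test recovered 100 of 100 genes changed by 1 and 70 of 100 genes changed by 0.5. It made 16 false calls (8.60% of its calls). Real genes are correlated and many are lower, so these rates need not hold for the real data. Without names, the fixed rule allowed at most 2 identifiers that rose and 2 that fell. They are those with the largest change among called genes whose groups do not overlap and whose higher group averages at least 5 FPKM.

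Single measures per library were compared with exact two-sided permutation tests, which cannot go below 0.1 with 3 libraries per group. Shares of identifiers were compared with two-sided Fisher's exact tests with 95% intervals; identifiers are not independent replicates. Clustering along chromosomes was tested by shuffling calls within chromosomes (10000 shuffles for neighbouring pairs, 1000 for windows of 50 tested identifiers). The subgenome, chromosome, newGene, abundance, neighbour and window comparisons were chosen after the data had been seen. The window scan was added after several of the largest falls had been seen to lie close together on D05. Replicate numbers were checked for pairing. The correlations of same-numbered control and PS-COOH libraries, after removing group means, were -0.073, -0.061 and -0.0073, so the numbers do not pair the libraries. No pair of libraries shared more than 1 identical value above 0, so none was a copy of another. Alternatives were the pseudocount, the filter, 2 scalings, the prior, library weights, a replicate block and leaving out each library. Figures were drawn with matplotlib 3.10.9.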

Results

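Root transcriptomes were compared between 3 control libraries and 3 libraries from cotton exposed to 300 mg/l PS-COOH for 9 days, to ask which genes differ in expression after the exposure. Each library had between 63090 and 65242 identifiers above 0 FPKM, and 11040 of the 81166 identifiers were at 0 in every library. Over the tested genes, log2(FPKM + 1) values correlated at 0.984 to 0.988 (Pearson's r across genes) between libraries of a group and at 0.947 to 0.958 between libraries of different groups. The first principal component held 66.9% of the variance and separated the groups, and the second held 9.58%.

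PS-COOH exposure was accompanied by changes in a large part of the root transcriptome. Of the 45258 tested genes, 7117 rose and 6825 fell in the PS-COOH libraries (limma, adjusted p under 0.05), which is 30.8% of the genes tested, and 31316 did not pass. Most of these changes were small on the log2(FPKM + 1) scale, which understates the change of low genes. The median size of a called change was 0.43 on that scale, and 71.8% of the called genes changed by less than 1.5-fold on it. The 3 control and 3 PS-COOH values did not overlap in 44.5% of all tested genes, where chance alone gives 10%. They did not overlap in 13644 of the called genes (97.9%), which were selected on the same values. Which direction was more frequent overall depended on the processing, since 6616 genes rose and 7229 fell under quantile normalization, and 4845 rose and 5072 fell with a filter of 5 FPKM.

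Large changes were mostly increases. At least 2-fold changes on the log2(FPKM + 1) scale were found in 842 genes that rose and 259 that fell, so rises made up 76.5% of them, against 48.9% of the called changes under 2-fold. At 4-fold or more, 55 genes rose and 29 fell. The excess of rises held at high abundance: among genes averaging at least 10 FPKM, 250 rose and 61 fell at least 2-fold. Called changes were more frequent in abundant genes. They made up 21.3% of the genes under 2 FPKM and 71.1% of the 554 genes at 100 FPKM or more, of which 242 rose and 152 fell. The chance of passing the test also differs with abundance, and the pseudocount shrinks the changes of low genes. These shares therefore do not show that abundant genes responded more. The 2-fold counts depend on the pseudocount, with 1703 rises and 572 falls at a pseudocount of 0.1.

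**Figure D1:**
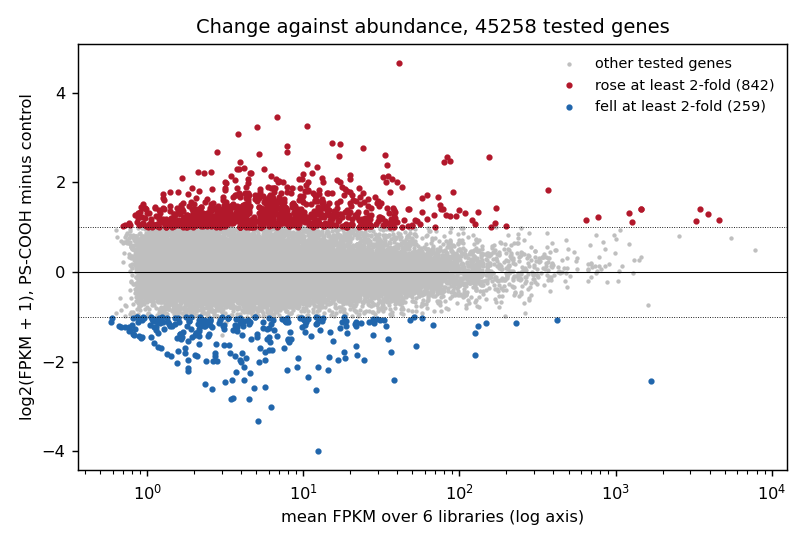
Change in expression (log2(FPKM + 1), PS-COOH minus control, vertical axis) against mean FPKM over the 6 libraries (logarithmic horizontal axis) for each of the 45258 tested genes. Coloured points changed at least 2-fold at an adjusted p under 0.05, 842 of them upwards and 259 downwards, and dotted lines mark a 2-fold change.

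The gene with the largest rise under the fixed rule was Gohir.A04G039105.v2.1, on chromosome code A04. It averaged 0.251 ± 0.114 FPKM in the control libraries and 82.0 ± 91.3 FPKM in the PS-COOH libraries (SD, n = 3 each), a log2 difference of 4.66 with a standard error of 1.05 (limma, adjusted p = 0.0050). Its PS-COOH libraries lay far apart, at 1.67, 181 and 63.2 FPKM. The log2 difference was 6.44 without PS-COOH replicate 1 and 3.39 without PS-COOH replicate 2, and the call was lost with a robust prior (adjusted p = 0.13, against 1.6e-07 to 0.042 over the other limma alternatives). Gohir.D07G038133.v2.1, on D07, rose evenly in the 3 libraries, from 0.298 ± 0.249 to 13.2 ± 0.741 FPKM. The means differed 44.4-fold, a ratio that rests on control values near 0 (0.584, 0.161 and 0.147 FPKM). The log2 difference was 3.47 ± 0.13 (SE, limma, adjusted p = 4.9e-09).

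The largest fall on the log2(FPKM + 1) scale under the fixed rule was that of Gohir.D01G179700.v2.1, on D01, from 24.4 ± 2.02 FPKM in the control to 0.592 ± 0.0523 FPKM in the PS-COOH libraries. That is a 41.1-fold difference of means and a log2 difference of -3.99 ± 0.096 (SE; limma, adjusted p = 1.4e-10). Gohir.D05G373000.v2.1, on D05, fell from 10.2 ± 1.14 to 0.107 ± 0.109 FPKM, a 94.8-fold difference of means, with a log2 difference of -3.34 ± 0.13 (SE; limma, adjusted p = 4.0e-09). It was listed at 0 in PS-COOH replicate 1, and it lies in a part of D05 where called genes are dense, described with the chromosomes.

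The most abundant transcripts took a larger share of the transcriptome in PS-COOH roots. The 10 most abundant genes of each library held 4.92 ± 0.241% of the summed FPKM in the control libraries and 7.74 ± 0.241% in the PS-COOH libraries (SD, n = 3 each), with no overlap (exact permutation p = 0.1, the smallest possible). The summed FPKM over all genes was 562920 ± 4830 in the control and 603559 ± 6072 in the PS-COOH libraries (SD, n = 3 each, exact permutation p = 0.1). FPKM is scaled to the mapped fragments of each library, so a higher sum does not show more RNA. The 10 genes most abundant over the 6 libraries accounted for 42.8% of the net gain in this sum. Of those 10 genes, 8 rose and 2 fell. Of the 100 most abundant, 59 rose, 13 fell and 28 did not pass.

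**Figure D2:**
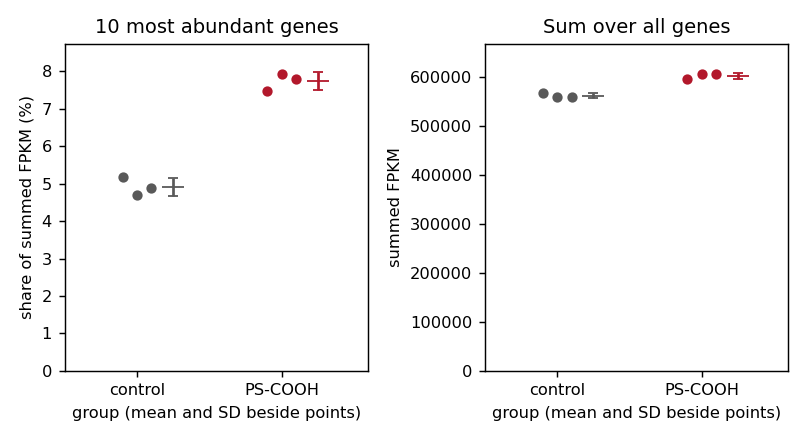
Share of summed FPKM held by the 10 most abundant genes of each library (left, percent) and summed FPKM over all identifiers (right), with 1 point per library and the mean and SD beside the points. The PS-COOH libraries lie above the control libraries in both, at 7.74% against 4.92% and at 603559 against 562920 FPKM. The sum is no measure of total RNA, since FPKM is scaled to the mapped fragments of each library.

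The most abundant gene of all, on A13, rose from 6523 ± 545 to 9104 ± 576 FPKM (SD, n = 3 each), a log2 difference of 0.48 (limma, adjusted p = 8.2e-05). A gene on D13 rose from 4081 ± 325 to 6955 ± 541 FPKM. The third most abundant gene, on A04, rose from 2838 ± 170 to 6366 ± 188 FPKM, a ratio of 2.24, and the fifth, on A05, rose from 1912 ± 89.6 to 5061 ± 196 FPKM, a ratio of 2.65. The 9 most abundant of the genes that rose at least 2-fold all carry an A04 or an A05 code. Of these 9, 8 belong to a pair of runs of neighbouring identifiers that rose, 6 on A04, whose summed FPKM went from 8409 to 19209, and 4 on A05, whose sum went from 3404 to 8905. Gene sequences were not used here. Where neighbours are near-identical copies, their reads cannot be told apart, and the level of each single copy is uncertain.

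The most abundant gene that fell, on D05, dropped from 2870 ± 99.2 to 528 ± 40.5 FPKM, a 5.44-fold difference with a log2 difference of -2.44 (limma, adjusted p = 5.9e-11). It lies in the same part of D05 as Gohir.D05G373000.v2.1. The next, on A10, fell from 2009 ± 67.3 to 1206 ± 49.7 FPKM, a ratio of 1.67. The third, on A03, fell from 1116 ± 22.8 to 965 ± 72.9 FPKM. Among genes that fell at least 2-fold, the second most abundant, on A09, went from 569 ± 8.51 to 269.7 ± 1.30 FPKM, and the third, on D06, from 318 ± 3.24 to 145 ± 8.47 FPKM.

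The subgenomes responded in similar proportions. Among identifiers with an A code, 377 of 20804 rose at least 2-fold (1.81%), and among those with a D code 420 of 21554 did (1.95%), an odds ratio of 0.93 with a 95% interval from 0.80 to 1.07 (Fisher's exact test, p = 0.32, Benjamini-Hochberg adjusted p = 0.38 over 6 tests). Falls of at least 2-fold occurred in 99 A and 114 D identifiers, an odds ratio of 0.90 with an interval from 0.68 to 1.19 (Fisher's exact test, p = 0.45). These intervals leave room for modest differences. No chromosome passed adjustment over the 52 Fisher tests of 2-fold rises and falls by chromosome, and 4 of the tests had an unadjusted p under 0.05. A04 had the largest share of 2-fold rises, 31 of 931 identifiers (3.33%) against 1.85% elsewhere (Fisher's exact test, p = 0.0030, adjusted p = 0.16). Without the runs of at least 3 neighbours that changed in 1 direction, A04 had 22 of 922 (2.39%) against 1.76% elsewhere.

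Identifiers called newGene differed from the rest. Only 161 of the 2776 tested rose (5.80%), against 16.4% of the other identifiers, an odds ratio of 0.31 (interval 0.27 to 0.37; Fisher's exact test, p = 2.3e-61, adjusted p = 1.4e-60). Falls of at least 2-fold were more frequent among them, 46 (1.66%) against 0.50%, an odds ratio of 3.34 (interval 2.37 to 4.63; Fisher's exact test, p = 7.6e-11, adjusted p = 2.3e-10), with 77 at a pseudocount of 0.1 and 12 with a filter of 5 FPKM. Falls of any size were not more frequent, 380 (13.7%) against 15.2%, an odds ratio of 0.89 (interval 0.79 to 0.99; Fisher's exact test, p = 0.035, adjusted p = 0.070). Their 2-fold rises, 42 (1.51%), did not differ detectably from the 1.88% of the others (Fisher's exact test, p = 0.19). The newGene identifiers were less abundant, with a median of 2.56 FPKM against 5.10. Their median within-group SD was larger, 0.163 against 0.117. The shares that rose or fell by any size were not matched on either. A lower chance of passing the test was therefore not separated from a difference in response. Of 10 identifiers listed at 0 in all PS-COOH libraries and at 1 FPKM or more in each control library, 9 were newGene. In the other direction there were 4 such identifiers, of which 1 was newGene.

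Genes with large changes lay next to each other more often than in shuffled order. In number order, 87 neighbouring pairs of tested identifiers both rose at least 2-fold, where shuffling within chromosomes gave 15.2 on average and at most 32, and 19 pairs both fell, against 1.15 on average and at most 7 (permutation p = 0.0001 for each, the smallest that 10000 shuffles can give). A further 18 pairs held 1 gene that rose and 1 that fell at least 2-fold, a count that was not compared with shuffles. There were 14 runs of at least 3 neighbours that rose and 2 that fell, holding 55 identifiers. In 8 of the 16 runs at least 1 member differed from the rest of its run in its change on the log2(FPKM + 1) scale (limma, adjusted p under 0.05), but not in the A04 run of 6 or the A05 run of 4. On that scale equal proportional changes differ between low and higher genes, and unequal ones can look alike. The lack of a difference in the A04 and A05 runs therefore does not show that their members changed in equal proportion. The fall runs were both on D05. One held 5 genes whose FPKM summed to 7.67 in the control and 0.138 in the PS-COOH libraries, and the other held 3 genes, including Gohir.D05G373000.v2.1, whose sum went from 21.9 to 3.30.

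By the count in windows of 50 tested identifiers, 2-fold calls peaked toward the end of D05, a region noticed from its falls of at least 10-fold and then scanned for. The highest window there held 19 genes changed at least 2-fold, where the highest window anywhere in 1000 shuffles held 11 (permutation p = 0.001, the smallest possible). The segment spans the tested identifiers ranked 2328 to 2413 of the 2463 on D05. Of its 86 genes, 25 changed at least 2-fold, and they went both ways, with 12 that rose and 13 that fell. In proportion 2.05 would have changed so, but the segment was picked by its density of such calls. Its excess was therefore given in advance and tests nothing. A further 35 of the 86 did not pass the test. With a filter of 5 FPKM, 5 rose and 3 fell at least 2-fold. Runs of neighbours that shared a direction held 11 of the 25, 8 of them falls. Means differed at least 10-fold in 13 of the 25, of which 3 rose and 10 fell, against 56 of 985 (5.69%) of the other 2-fold calls with a chromosome code. No p-value is given for this difference, because such changes drew attention to the segment. A second segment lay on D13, and its highest window held 10 calls (permutation p = 0.0090), against 19 on D05. It had 10 genes changed at least 2-fold among 34 identifiers, of which 9 rose and 1 fell, and none reached 10-fold. Both segments were picked by their density of 2-fold calls, so the share of calls within each does not compare them.

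**Figure D3:**
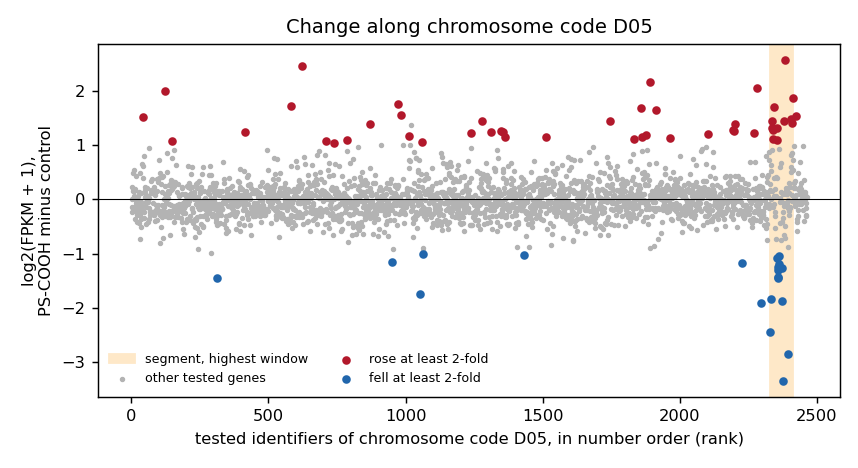
Change in expression (log2(FPKM + 1), PS-COOH minus control) of the tested identifiers with a D05 code, in number order along the horizontal axis (rank 1 to 2463). The shaded segment, ranks 2328 to 2413, holds 12 genes that rose (red) and 13 that fell (blue) at least 2-fold.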

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

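The pseudocount, filter, scaling, prior, weight, block and leave-one-out alternatives were planned before the data were examined; the restrictions to abundant genes, to chromosome- or scaffold-coded identifiers, to genes outside runs or dense segments, and to shares of the top 1 and top 50 genes were chosen after the data were seen. The overall counts of rises and falls stayed within 1.5 times the reported one except these. A pseudocount of 0.1 gave 1703 rises and 572 falls of at least 2-fold, and 0.5 gave 396 such falls, because a smaller pseudocount shrinks low genes less. Requiring 5 FPKM in 3 libraries left 553 and 131 of them, since fewer genes were tested. Keeping only genes averaging at least 10 FPKM left 2954 rises and 2705 falls in all, 250 and 61 of them 2-fold. The restrictions to some of the genes, made after the data were seen, count parts of the reported calls and are not new tests. Rises stayed between 73.7% (quantile normalization) and 80.8% (5 FPKM filter) of the 2-fold calls. Among all calls they were 51.0% as reported, 47.8% under quantile normalization and 48.9% under the 5 FPKM filter (4845 rises, 5072 falls), so which direction was more frequent overall is not settled. The 46 newGene falls of at least 2-fold became 77 (2.77%, against 1.17% of the others) at a pseudocount of 0.1 and 12 (1.76% against 0.535%) under the 5 FPKM filter. The rise in the share of summed FPKM was 2.82 percentage points for the top 10 genes, 0.349 for the top gene and 3.79 for the top 50. The D05 segment held 11 to 13 rises and 12 or 13 falls of at least 2-fold when each library was left out, but 5 and 3 under the 5 FPKM filter, since many of its genes are low. Median-ratio scaling gave 7520 rises and 6297 falls. Leaving out each library in turn gave 5599 to 6620 rises, 4891 to 6199 falls, and 834 to 889 and 262 to 282 at least 2-fold. With a replicate block, on numbers that do not pair the libraries, 6687 genes rose and 6014 fell, 844 and 259 at least 2-fold; no control library correlated best with the PS-COOH library of its own number. Gohir.A04G039105.v2.1 lost its call under a robust prior (log2 difference 4.66, adjusted p = 0.13 against 1.6e-07 to 0.042 under its other limma alternatives) and was not tested under the 5 FPKM filter. The other named genes kept their calls where included, which leaves out some of the later restrictions, and none of the 4 changed direction there. The later restrictions could not change a call. The planned gene list tests (camera, its estimated correlation, and fry) were not run because no identifier could be named. Depth is known only relative to other libraries, so changes in genes near 0 FPKM are the least certain.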

Other observations

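All 3 patterns weighed here were noticed in these data, and the test of a shift of all genes and the tests of the D05 segment were chosen only after the result was seen. The real grouping of the 6 libraries called 13942 genes, 1101 of them at least 2-fold, and the highest count of any other split into 3 and 3 was 1 gene for each. The 10 splits are too few for a share under 0.05.

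The dense segment near the end of D05 held 12 rises and 13 falls of at least 2-fold, and 3 rises and 10 falls of at least 10-fold. Placement of each call independently of the others is argued against by its window of 19 calls among 50 identifiers, above the 11 of any shuffle. Neighbours on all chromosomes changed together more often than in shuffles, so this does not show more than such local grouping. The scan also counted the falls that had prompted it. A single direction over the whole segment is argued against by the 48.0% of its 2-fold calls that go against its main direction, although shorter runs of 1 direction held 11 of the 25. A sequence difference between the plants of the groups, with copies unlike the reference, is a candidate explanation that these values cannot decide. The odds ratio of 17.8 for changes of at least 10-fold is not counted for it, because the segment was noticed from such changes. Of the segment's 13 genes of that size, 0 are at 0 in all libraries of a group. That count decides nothing about absence, since values can lie near 0 without reaching it in every library. Gohir.D05G373000.v2.1, for example, was at 0, 0.218 and 0.105 FPKM in the PS-COOH libraries. The odds ratio was 9.65 when the D13 segment, with none of at least 10-fold, was first pooled with the D05 segment. D05 was set apart after that was seen. A response of this region to PS-COOH also stays open and untested.

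More large rises than large falls is the second pattern. Scaling between libraries is argued against, since rises were at least 73.7% of the 2-fold calls under median-ratio and quantile scaling. Values near the floor are argued against by the 80.4% among genes averaging at least 10 FPKM. A shift of all genes stays open, since FPKM removes it and the 48.9% among changes under 2-fold decides nothing. A response to PS-COOH, and any difference in growth, harvest or batch that went with the groups, stay open, because the design does not separate them.

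The third pattern is the excess of 2-fold falls among newGene identifiers, 46 of 2776, while falls of any size were 13.7% against 15.2% in the others. Their lower abundance does not account for all of it, since other identifiers matched on mean FPKM gave 15.6 falls on average and at most 33 in 10000 draws. Matching also on the spread between replicates gave 18.7 on average and at most 40. For rises there was no excess, with 42 seen and 48.5 on average in matched draws. How these loci were defined is not given in the sources used here, so an effect of how they were assembled, or of sequence differences from the reference, was not tested.

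Runs of neighbouring genes were also tested, in comparisons chosen after the data had been seen, and no cause is weighed for them. The 87 neighbouring pairs that both rose exceeded the 32 of any shuffle. Whether members of a run changed in fixed proportion was tested on the log2(FPKM + 1) scale, which distorts proportions in low genes, so that test decides nothing about reads shared between copies.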
